A study of Rattus norvegicus with 9 samples.

How the data were processed

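Kidney cortex from diabetic ZDF fa/fa rats labelled Medical Bypass had been flash frozen, RNA isolated with a column kit, and stranded mRNA libraries prepared on an automated system. The submitters' processing notes name FastQC 0.11.2, MultiQC 0.9, HTSeq 0.6.1p1 for counting, DESeq2 and the genome build Rnor_5.0. The aligner and the version of DESeq2 are not given in the sources used here. The deposited values are a signal made by the authors: gene read counts divided by each library's size factor, not corrected for gene length. Whole reads were recovered from them, since low values in each library were multiples of the value of 1 read. Between 99.988% and 99.994% of the values above 0 lay within 0.1 read of a whole number, and the size factors averaged 1.19 ± 0.415 (SD, n = 9).

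The table held 18423 rows, of which 18420 named genes and 3 counted reads outside genes, reads in more than 1 gene and reads aligned to more than 1 place. Those 3 were left out of the gene tests and used only to describe the libraries. As shares of all counted reads, reads outside genes made 28.9% ± 2.93 and reads aligned to more than 1 place 17.2% ± 2.33 (SD, n = 9). Shares of reads in a single library carry Wilson 95% intervals, which cover counting error only. Values were 0 in all 9 libraries for 265 genes. Gene symbols were taken as listed, with a hyphen restored in 49 names, and 2364 rows known only by an Ensembl identifier were given no symbol. The table gives no positions, so none are reported. The labels state no drugs, doses, times, sex or batch, and none was assumed. Correlations between pairs of libraries on log2 values ran from 0.939 to 0.993 over 36 pairs. Their read counts differed by more than counting error in every pair, so no 2 libraries were copies of each other. The chi-square per degree of freedom, near 1 for counting error alone, was 19.3 to 191.4.

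All 9 samples formed the 1 group the labels give. Apart from parts said to be added later, the tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. Values were analysed as log2 of the value plus 1 for the 13647 genes with a mean of at least 10, which were 74.1% of the genes. Variability was tested with limma 3.58.1 in R 4.3.3, comparing each gene's variance with a robust trend of variance on level. The 35 fixed lists held 422 genes, of which 347 were matched in the table, and 31 lists had at least 3 tested members. They covered tubular injury, extracellular matrix, podocyte, mesangium and smooth muscle, endothelium, the proximal tubule S1 and S2 and S3 segments, thick ascending limb, distal convoluted and connecting tubule, collecting duct principal cell, intercalated cell, medulla, macrophage, lymphocyte, MHC class II, interferon response, NF-kB and chemokine, complement, fatty acid oxidation, oxidative phosphorylation, mitochondrial genome, cholesterol synthesis, lipogenesis, gluconeogenesis and fructose use, renin-angiotensin, oxidative stress, ER stress, hypoxia, immediate early, cell cycle, circadian clock, blood, adipose, adrenal and skeletal muscle genes. No gene was in more than 1 list. Coordination of a list was its mean pairwise Pearson correlation, set against 10000 random lists of the same size drawn from 20 bins of mean level. A separate draw of 10000 random lists made in the same way gave the percentile of a list's spread.

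The tubular injury score was the mean of the members' z-scores, and the score of every other list was made the same way. Relations between scores were tested with two-sided exact permutation tests over all pairings. With a covariate, the residuals of both scores were permuted instead, which makes the p-value approximate. Slopes of single genes on the injury score, in SD units of the score, were fitted with limma with a robust trend, leaving out the members of the injury list, and again over 100 random permutations of the score. The same slopes were fitted to the recovered reads with edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0. Lists were tested on the slopes with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The Benjamini-Hochberg method adjusted p-values within each family, with a threshold of 0.05.

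Named genes were chosen by a rule: the measured members of the injury list, the 2 most abundant members and the most variable member of every other list, the 10 genes with the largest slope statistics where none passed, and the 15 genes with the highest means. Genes named outside it are said to be so, and the values of some genes under the rule are not reported here. Alternatives covered the pseudocount (0.5 and 5), the filter on low values, TMM scaling, the same total per library, each replicate left out in turn, Havcr1 alone or the first principal component as the injury measure, library size as a covariate, Spearman rho, and the other tools. The share of reads aligned to more than 1 place as a covariate, and replicates 4 to 9 alone, were added after the data were seen. Relations of the scores to that share were also added then. A planned medulla score as a covariate was not run, since 1 member of that list could be tested.

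The procedure was tested on simulated data of the same size. With a slope of 1 log2 unit per SD of the score, 99 of 100 genes were called, and with a slope of 0.5, 37 of 100, while 3 of 13147 unchanged genes were called. Genes given an extra SD of 1 log2 unit were called in 81 of 100 cases, with 8 of 13147 unchanged genes called. All 10 simulated lists with a shared factor were called and 0 of 10 without it. The simulated variances followed the trend closely and the measured ones scattered more widely (limma prior degrees of freedom 4.48), so these rates hold for the simulated variances and not for the measured ones. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 was used to read the table and draw the figures.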

Results

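Messenger RNA was sequenced from the kidney cortex of diabetic ZDF fa/fa rats, an obese strain that lacks a working leptin receptor and develops type 2 diabetes with kidney disease. All 9 libraries analysed here carry the same label, Medical Bypass, a treatment set against gastric bypass surgery in the study's title, and they form 1 group of 9 replicates. The stated question was the renal transcriptome of kidney disease in this strain and the effect of the treatment on it. No untreated, operated or healthy group was analysed here, so no treatment effect could be estimated, and the comparisons below are between the replicates of the 1 group. The labels do not say whether the replicates are separate animals. The p-values then measure only the spread between these samples, which may be technical. Reads in genes numbered 26045365 ± 9955332 per library (mean ± SD, n = 9) and ranged from 10757440 in replicate 3 to 43071223 in replicate 8. Between 15752 and 17052 genes had at least 1 read in a library. Every gene level below is a read count divided by the library's size factor, given as mean ± SD over the 9 replicates, and 1 read was worth 0.544 to 1.99 such units.

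Transcripts of the proximal tubule, the segment that reabsorbs most of the filtered load, were among the most abundant in the cortex. Pck1, the rate-limiting enzyme of renal gluconeogenesis, had the highest mean level at 229757 ± 54281. Cyp4a2, a fatty acid hydroxylase, averaged 152505 ± 24748. The sodium pump subunit Atp1b1 stood at 100081 ± 10104 and the phosphate transporter Slc34a1 at 79242 ± 21463. Among the 15 genes with the highest means were also Atp5f1b, Fth1, Eef1a1, Ctsb, Ndrg1, Ehhadh, Miox and Atp5f1a, at means between 64535 and 104140. Eef1a1 differed 1.25-fold between its highest and lowest replicate and Ndrg1 4.11-fold. Together the 15 genes took 7.44% ± 0.611 of the reads in genes (SD, n = 9).

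Markers of injured tubule cells were present at widely different levels. Havcr1, which encodes the injury marker KIM-1, averaged 269.9 ± 133.0 and differed 6.18-fold between replicates, from 76.9 in replicate 7 to 475.1 in replicate 9. Spp1, encoding osteopontin, averaged 14576 ± 4256 and Clu, encoding clusterin, 10225 ± 2053. The simple epithelial keratins Krt8, Krt18 and Krt19 averaged 5171 ± 1024, 581.0 ± 251.2 and 191.9 ± 42.3. Vcam1 averaged 496.8 ± 96.1, Timp1 144.8 ± 33.8, Sox9 815.3 ± 201.2 and Cd44 388.1 ± 74.8. Lcn2, encoding the injury marker NGAL, averaged 7.53 ± 4.28, under the minimum mean of 10 set for testing, and Krt20 was not matched in the table. These genes did not move as a block: the mean pairwise correlation of the 10 tested members was 0.0325 (adjusted p = 0.284 against random lists of like level), with Havcr1 and Cd44 at 0.811 and Krt18 and Sox9 at -0.839, across-sample correlations described here without a test. The tubular injury score, the mean of the members' z-scores in SD units of the score, was lowest in replicate 3 at -1.45 and replicate 2 at -1.28, and highest in replicate 8 at 1.22. Across replicates its r was 0.755 with Clu, 0.739 with Spp1 and 0.712 with Timp1. With Havcr1, Vcam1, Krt18 and Krt19 it was 0.407 to 0.472, and with Cd44, Krt8 and Sox9 -0.0223, -0.0492 and -0.2755. These values are described without a test, and the score does not stand for each of its members.

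Which single genes differed more between replicates than genes of like level was asked first. The largest ratios of variance to the trend belonged to Hmox1, the haem-degrading stress enzyme, at 55.1, with levels from 83.3 in replicate 1 to 3308 in replicate 9, a 39.7-fold range. Arntl, the core activator of the circadian clock, followed at 35.0 with levels from 33.8 to 1363. The S3-segment transporter Slc7a13 ranged from 689.7 to 11449 and the basolateral bicarbonate transporter Slc4a4 from 952.2 to 12330. Slc4a4 ran with a library measure, the share of reads aligned to more than 1 place. It stood at 5124 to 12330 in replicates 2, 3, 6 and 9, with shares of 14.9% to 15.8%. In the other replicates it stood at 952.2 to 2618, with shares of 16.8% to 22.1%. The cause was not tested. The clock repressors Nr1d1 and Nr1d2 and the clock output gene Dbp ranged 12.2-fold, 18.6-fold and 10.2-fold. Of 13647 genes tested, 0 passed limma's variance test after adjustment, with 573 at an unadjusted p under 0.05 and a lowest adjusted p of 0.957. These genes were picked after their values were seen.

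Coordination within gene groups was measured next, as the mean pairwise correlation of each fixed list's members across replicates against random lists of like level. Of 31 lists scored, 13 were coordinated at an adjusted p under 0.05. Genes are not independent replicates, so these p-values compare lists with lists.

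Immune and matrix genes formed part of that set. The MHC class II genes, which present antigen, moved together most closely, with a mean pairwise r of 0.812 (adjusted p = 0.0031). Cd74 averaged 22347 ± 5084 and RT1-Db1 4980 ± 1170, and the list mean differed 1.67-fold between its highest and lowest replicate. The macrophage list had a mean pairwise r of 0.373 (adjusted p = 0.00542), with the lysozyme gene Lyz2 at 5906 ± 727.7 and the complement component C1qc at 444.8 ± 155.3. NF-kB and chemokine genes reached 0.194 (adjusted p = 0.031), with Cxcl16 at 2953 ± 302.4. Extracellular matrix genes reached 0.221 (adjusted p = 0.0120), with Sparc at 9956 ± 1571, fibronectin Fn1 at 1364 ± 231.0 and the collagen cross-linker Lox at 45.1 ± 27.5. Relations of the list scores to the share of reads aligned to more than 1 place were examined only after the data were seen. The macrophage score was the 1 of 31 list scores that followed that share after adjustment, just under the threshold. Its Pearson r was 0.866 (exact permutation p = 0.00161, adjusted p = 0.0499), its Spearman rho 0.717 (exact permutation p = 0.0369), and r without the 2 replicates farthest from the median share 0.769. Other lists ran close to it without passing. MHC class II had an r of 0.699, NF-kB 0.7055 and adipose 0.747 (each exact permutation adjusted p = 0.198), and oxidative phosphorylation 0.652 (adjusted p = 0.278). Without the 2 farthest replicates these were 0.847, 0.728, 0.0954 and 0.925. The circadian clock score ran against the share, with an r of -0.716 (exact permutation adjusted p = 0.198), and -0.879 without those 2 replicates. With that share as a covariate, a setting added after the data were seen, the macrophage list fell to 0.155 (adjusted p = 0.0858) and the NF-kB list to 0.124 (adjusted p = 0.124). Without replicate 1 the NF-kB list stood at 0.234 with an adjusted p of 0.0527. It also missed the threshold without replicates 2, 3 or 7, at adjusted p between 0.0503 and 0.0649, with a mean of at least 100, at 0.122 (adjusted p = 0.148), and with each library scaled to the same total, at 0.147 (adjusted p = 0.210).

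Metabolic gene groups formed the largest part of the set. Cholesterol synthesis genes had a mean pairwise r of 0.509 (adjusted p = 0.0031) and a list mean that differed 2.03-fold between replicates. Every one of replicates 1 to 3, at mean log2 levels of 9.64 to 9.89, lay below replicates 4 to 9, at 10.13 to 10.66, and within replicates 4 to 9, a setting added after the data were seen, the mean pairwise r was 0.284 (adjusted p = 0.0349). Of 31 list means, 3 (9.68%) parted these sets without overlap, against 428 of 13647 genes tested (3.14%). The other lists that did were circadian clock and skeletal muscle. Fdps, which makes farnesyl diphosphate, averaged 3784 ± 1315 and differed 2.68-fold. Lipogenesis genes reached 0.320 (adjusted p = 0.0242), with their regulator Srebf1 at 2317 ± 814.7. Fatty acid oxidation genes reached 0.434 (adjusted p = 0.0109), with the peroxisomal enzyme Ehhadh at 73431 ± 13745 and the fuel switch Pdk4 at 24281 ± 13598. Genes of gluconeogenesis and fructose use reached 0.636 (adjusted p = 0.0202), with the fructokinase Khk at 10378 ± 2952. Oxidative phosphorylation genes reached 0.453 (adjusted p = 0.0491), with Cox4i1 at 22917 ± 8410. Immediate early genes, not a metabolic group, respond to stimuli within minutes and are also raised by tissue handling. They reached 0.612 (adjusted p = 0.00517), and their list mean differed 2.73-fold. Whether handling differed between replicates was not tested. Egr1 ranged from 4047 to 15207 and Atf3 from 148.7 to 1368. Without replicate 1, fatty acid oxidation stood at 0.0947 (adjusted p = 0.586), oxidative phosphorylation at 0.390 (adjusted p = 0.107), lipogenesis at 0.264 (adjusted p = 0.0754) and gluconeogenesis and fructose use at 0.624 (adjusted p = 0.0562). Oxidative phosphorylation also missed the threshold without replicates 2, 4 or 6, and lipogenesis without replicate 6. With each library scaled to the same total, oxidative phosphorylation fell to 0.170 (adjusted p = 0.0874) and lipogenesis stood at 0.304 (adjusted p = 0.0531), and with a mean of at least 100 they stood at 0.453 (adjusted p = 0.0573) and 0.214 (adjusted p = 0.125).

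Markers of the nephron's cell types made up the rest. Intercalated cell genes, which secrete acid or base, had a mean pairwise r of 0.630 (adjusted p = 0.00868), with the proton pump subunit Atp6v1b1 at 4928 ± 1083. Collecting duct principal cell genes reached 0.458 (adjusted p = 0.0111), with the glucocorticoid-inactivating enzyme Hsd11b2 at 7776 ± 3191, and podocyte genes 0.368 (adjusted p = 0.0127), with Podxl at 5374 ± 900.7. The highest replicate of the intercalated and principal cell lists was replicate 1, at z-scores of 1.87 and 1.81, where the lists of the proximal tubule S1 and S2 segments and of fatty acid oxidation were lowest, at -1.43 and -1.67. Without replicate 1, the principal cell list stood at 0.0451 (adjusted p = 0.333), the intercalated list at 0.310 (adjusted p = 0.107) and the podocyte list at 0.275 (adjusted p = 0.0562). The 5 lists that passed without it were extracellular matrix, macrophage, MHC class II, cholesterol synthesis and immediate early. Of these, all but extracellular matrix passed in replicates 4 to 9 alone, and no other list did.

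The remaining 18 lists did not pass, tubular injury among them. The proximal tubule S1 and S2 list had a mean pairwise r of 0.347 (adjusted p = 0.0773). Its list mean differed 1.97-fold, but 1.28-fold without replicate 1, where it was lowest. The SD of that mean over all replicates was larger than in 100% of random lists of like level. The circadian clock list had a mean pairwise r of 0.127 (adjusted p = 0.0748), or 0.0363 (adjusted p = 0.327) in replicates 4 to 9 alone, a setting added after the data were seen. Members that move in opposite directions, as Arntl and Cry1 did against Nr1d1 and Dbp, lower this mean. It therefore cannot show whether the clock genes move together. Proximal tubule S3 stood at 0.240, thick ascending limb at 0.210 and distal convoluted and connecting tubule at 0.341, with Umod at 57070 ± 13125 and Calb1 at 21532 ± 7623. Mesangium and smooth muscle stood at 0.165, endothelium at 0.0456, lymphocyte at -0.350, interferon response at 0.0629 and complement at 0.277. The renin-angiotensin list stood at 0.162, oxidative stress at -0.0256, ER stress at 0.0817, hypoxia at -0.00880 and cell cycle at 0.0870. The adipose and skeletal muscle lists, which could mark tissue around the kidney, stood at 0.284 and 0.394, with Adipoq at 333.7 ± 64.7 and Mylpf at 21.9 ± 11.2. Adjusted p for these 18 lists ran from 0.0748 to 0.969. Some passed with the share of reads aligned to more than 1 place as a covariate, a setting added after the data were seen. These were proximal tubule S1 and S2 at 0.453 (adjusted p = 0.0238) and thick ascending limb at 0.357 (adjusted p = 0.0238). Distal convoluted and connecting tubule at 0.478 (adjusted p = 0.0300), mesangium and smooth muscle at 0.423 (adjusted p = 0.00542) and complement at 0.396 (adjusted p = 0.0138) also passed. The medulla, mitochondrial genome, blood and adrenal lists had fewer than 3 tested members and were not scored. Of their members, Akr1b1 of the medulla list averaged 604.8 ± 138.9, the haemoglobin gene Hba-a2 12229 ± 6683 and the adrenal gene Star 19.3 ± 6.23, and no gene of the mitochondrial genome was matched.

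**Figure D1:**
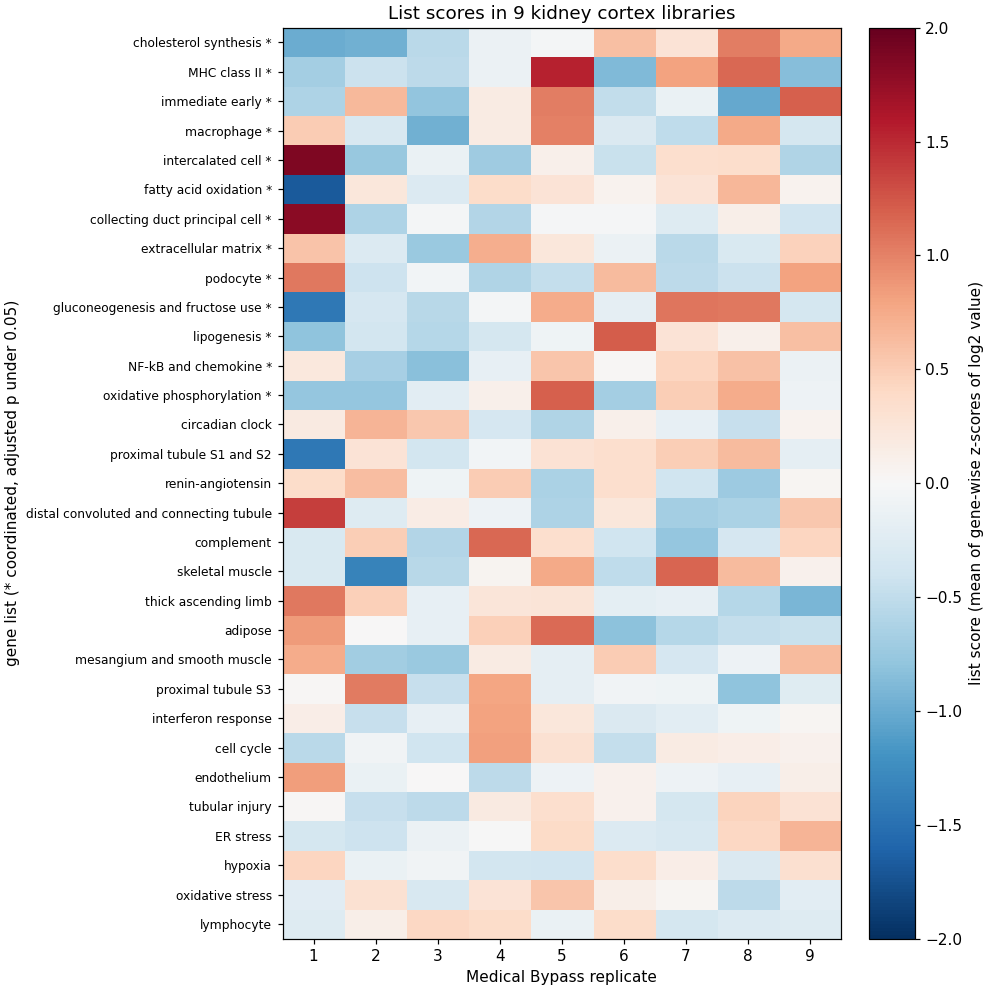
Each column is 1 of the 9 Medical Bypass replicates and each line a fixed gene list, coloured by the list score, the mean of its members' z-scores of log2 level, from blue below the mean to red above it. Asterisks mark the 13 coordinated lists; replicate 1 stands at 1.87 for intercalated cells and at -1.67 for fatty acid oxidation.

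Whether other gene groups followed the tubular injury score between replicates was the main relation fixed in advance. The macrophage score had a Pearson r of 0.759 with the injury score (exact permutation p = 0.0211, adjusted p = 0.264). Its Spearman rho was 0.733 (exact permutation p = 0.0311), and r without the 2 replicates farthest from the median injury score was 0.626. With the share of reads aligned to more than 1 place as a covariate, a setting added after the data were seen, its r was 0.681 (permutation p of the residuals = 0.0468, adjusted p = 0.420). That p is approximate, since residuals of a fit are not freely exchangeable. The injury score itself, also compared with that share only after the data were seen, had an r of 0.548 with it (exact permutation p = 0.121, adjusted p = 0.422). The Spearman rho was 0.60 (exact permutation p = 0.0968), and r without the 2 replicates farthest from the median share was 0.578. The extracellular matrix score had an r of 0.613 (exact permutation p = 0.0854, adjusted p = 0.367), a rho of 0.417 (exact permutation p = 0.270) and an r of 0.339 without those 2 replicates. The proximal tubule S1 and S2 score had an r of 0.109 (exact permutation p = 0.813, adjusted p = 0.938), a rho of 0.400 (exact permutation p = 0.291) and an r of 0.111 without them. The fatty acid oxidation score had an r of 0.197 (exact permutation p = 0.687, adjusted p = 0.888), a rho of 0.617 (exact permutation p = 0.0857) and an r of 0.279 without them. ER stress, the unfolded protein response genes with Hspa5 at 19914 ± 5507, had an r of 0.729 (exact permutation p = 0.0264, adjusted p = 0.264), a rho of 0.767 (exact permutation p = 0.0214) and an r of 0.779 without them.

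None of the 30 lists passed the two-sided exact permutation test after adjustment, and 3 had an unadjusted p under 0.05: macrophage, ER stress and circadian clock. Of the 14 clock genes, 8 parted replicates 1 to 3 from replicates 4 to 9 without overlap, such as the repressor Nr1d1 at 1309 to 1346 in the first set and 110.1 to 242.6 in the second, and 6 overlapped, such as Per2 at 2209 to 2599 and 1282 to 2929. A correlation pooled over both sets would not describe a relation within either, so none is reported as a result for that list. Within replicates 4 to 9 its r was -0.617 (exact permutation p = 0.211, adjusted p = 0.993, n = 6). The proximal tubule r turned to -0.398 and the fatty acid oxidation r to -0.333 when each library was scaled to the same total, and to -0.344 and -0.161 with log2 library size as a covariate. With Havcr1 alone as the injury measure the macrophage r was 0.0795, and with the first principal component of the injury list the extracellular matrix r was -0.0913.

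**Figure D2:**
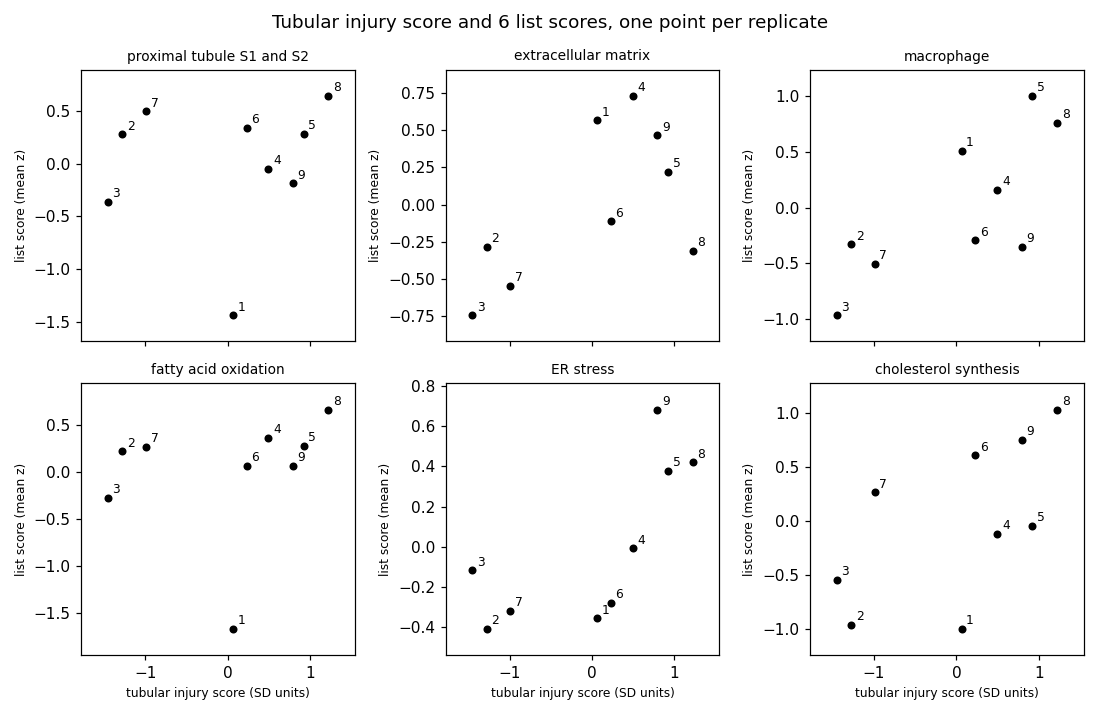
The tubular injury score in SD units is on the horizontal axis of each panel and the score of another list, as mean z-score, on the vertical axis, with 1 numbered point for each of the 9 replicates. The macrophage panel holds an r of 0.759 and the proximal tubule S1 and S2 panel an r of 0.109; replicate 1 lies apart at the bottom of the proximal tubule and fatty acid oxidation panels.

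**Figure D3:**
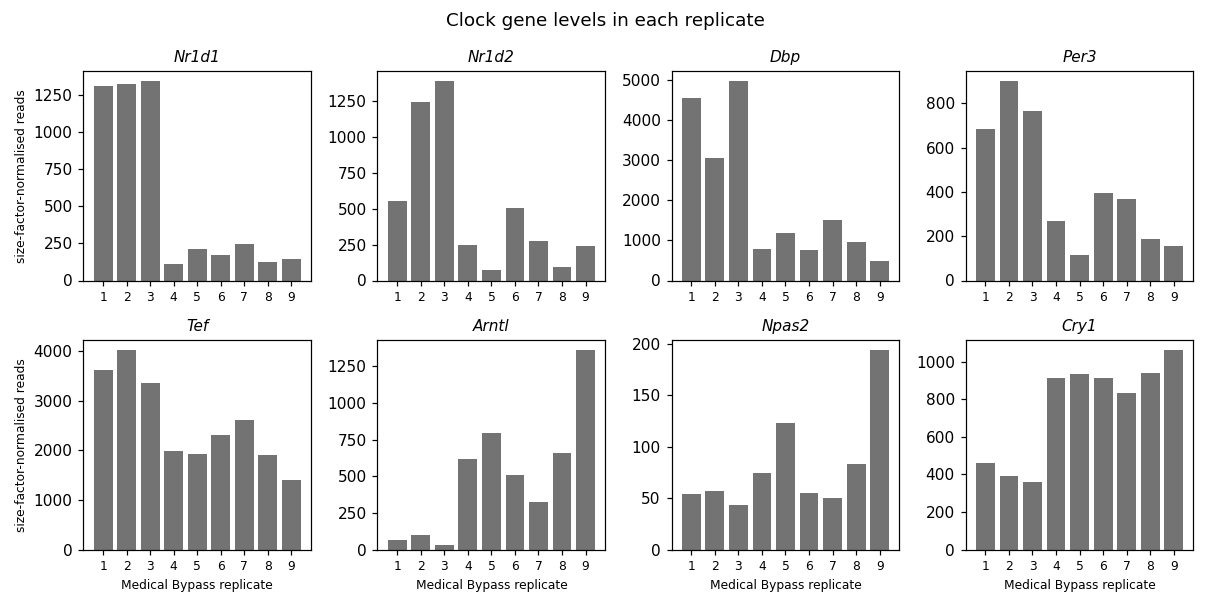
Each bar is the level of a clock gene in 1 of the 9 replicates, as reads divided by the size factor, on axes that start at 0; the genes were chosen after their values were seen. Nr1d1 lies at 1309 to 1346 in replicates 1 to 3 and at 110.1 to 242.6 in replicates 4 to 9, and Arntl runs the other way, from 33.8 in replicate 3 to 1363 in replicate 9.

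At the level of genes, the 10 largest slope statistics on the injury score belonged to varied functions, while the steepest slope was that of the clock gene Arntl, at 1.42 ± 0.34 log2 units per SD of the score (SE, n = 9). The slope of Ppard, a nuclear receptor for fatty acids, was 0.73 ± 0.12 log2 units per SD of the score (SE, n = 9). Cdkn1a, encoding the cell cycle inhibitor p21, had a slope of 0.73 ± 0.14, the smooth muscle gene Tagln 0.54 ± 0.12, the cholesterol synthesis enzyme Dhcr7 0.59 ± 0.12 and the ER gene Sdf2l1 0.59 ± 0.13. The clock genes Nr1d2 and Per3 had slopes of -1.21 ± 0.25 and -0.88 ± 0.18, over levels that were highest in replicates 1 to 3. Ddit4l2 and Epm2a had slopes of 1.16 ± 0.25 and -0.78 ± 0.16. Of the 10 genes, 5 parted replicates 1 to 3 from replicates 4 to 9 without overlap: Nr1d2, Per3, Ddit4l2 (17.9 to 30.8 against 83.4 to 289.2), Epm2a (116.2 to 169.2 against 27.1 to 108.7) and Dhcr7 (300.6 to 467.9 against 709.8 to 1301). The rest overlapped, among them Ppard (408.1 to 646.8 against 637.9 to 1988) and Cdkn1a (117.4 to 277.6 against 242.6 to 845.5). Tagln (1391 to 2955 against 2747 to 5365) and Sdf2l1 (157.3 to 357.9 against 318.3 to 794.3) did too. The slopes of all 10 pool both sets. None of the 10 genes with the largest statistics passed limma's test: their adjusted p was 0.712.

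Of 13637 genes tested with limma, 0 had a slope above 0 and 0 a slope below 0 after adjustment, with 324 and 230 at an unadjusted p under 0.05. Of 100 random permutations of the score, 23 gave at least 554 genes at that unadjusted level, and their median was 268.5. edgeR called 0 and 0 (290 and 237 unadjusted), while DESeq2 called 10 with a slope above 0 and 4 below (384 and 269 unadjusted). By DESeq2 the 10 included Ppard, Cdkn1a, Tagln, Dhcr7, Sdf2l1, Ddit4l2, Nfil3, Creb3l1 and Ndrg1, and the 4 were Nr1d2, Per3, Epm2a and Ciart. Of these 14 genes 8 parted the same replicates without overlap, Ndrg1, Nfil3 and Ciart besides the 5 above, against 428 of all 13647 genes. Nfil3, Creb3l1 and Ciart were named after their values were seen. Among 298 members of fixed lists, 15 passed when adjusted over the list alone and 0 when adjusted over all genes tested. These 15 included 9 clock genes, Dhcr7, Fdps, Tagln, Des and Sdf2l1, and 6 of them passed when adjusted over all 298 members. The clock gene slopes pool both sets of replicates, and replicates 2 and 3 held the 2 lowest injury scores. Des, Cry1, Nr1d1, Ciart, Dbp and Npas2 lie outside the rule and were counted after their values were seen.

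Shifts of whole lists along the score were tested with camera, which compares a list's slopes with those of other genes. At its preset correlation of 0.01 between genes 8 lists passed, and with an estimated correlation none did. Of the 18 cholesterol synthesis genes, 16 had slopes above 0, with a median of 0.22 log2 units per SD (camera adjusted p = 6.7e-06 at the preset, and adjusted p = 0.470 with an estimated correlation). These slopes also pool replicates 1 to 3 with replicates 4 to 9, which differed in cholesterol synthesis levels: the list score had an r of 0.612 with the injury score (exact permutation p = 0.0857, adjusted p = 0.367), a rho of 0.667 (exact permutation p = 0.0589) and an r of 0.332 without the 2 replicates farthest from the median injury score, and 0.240 in replicates 4 to 9 (exact permutation p = 0.626, adjusted p = 0.993, n = 6). Of 13 macrophage genes, 12 had slopes above 0, with a median of 0.17 (camera adjusted p = 1.52e-04, and adjusted p = 0.470 with an estimated correlation). Extracellular matrix genes had slopes above 0 in 13 of 16 and oxidative phosphorylation genes in 12 of 14, with camera adjusted p of 0.0143 and 0.0153, and adjusted p = 0.503 and 0.795 with an estimated correlation. Slopes were above 0 in 11 of 13 NF-kB and chemokine genes, 4 of 6 mesangium and smooth muscle genes and 9 of 12 ER stress genes, with camera adjusted p of 0.0153, 0.0390 and 0.0391, and each with adjusted p = 0.470 with an estimated correlation. The circadian clock list made up the 8 at adjusted p = 0.470 with an estimated correlation. Its slopes pool replicates 1 to 3 with replicates 4 to 9, which differed in clock gene levels, so they do not describe a relation within either set. Fry, which asks whether a list's genes move on balance 1 way, called 0 lists, and its test for change in either direction 0.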

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

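The limit used in this part was fixed before the data were examined, and the 4 library measures it was applied to were chosen afterwards. Of 155 library measures, list means and named genes, 8 had a highest or lowest replicate that stood apart from the nearest other by more of the whole range than Dixon's limit for 9 samples allows at the 95% level. Chance alone gives about 1 in 20, close to this number, but 7 of the 8 were in replicate 1.

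In replicate 1, the proximal tubule S1 and S2 list was lowest, with a gap of 0.634 of the whole range between it and the nearest other replicate, and the fatty acid oxidation list was lowest with a gap of 0.563. Ehhadh, a peroxisomal enzyme of fatty acid oxidation, was lowest there at 38439 against 72267 to 84463 in the others, a gap of 0.802 of the range of log2 values. Pck1, the gluconeogenic enzyme, was lowest at 122789, with a gap of 0.530. The same replicate was highest for the collecting duct principal cell list, with a gap of 0.635, for the endothelium list, with a gap of 0.558, and for the intercalated cell list, with a gap of 0.553. Lists share cells and pathways, so these 7 are not independent. No biological explanation was tested.

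In replicate 5, the share of counted reads that fell outside genes was lowest at 22.0% (95% Wilson interval 22.017% to 22.039%, counting error only), with a gap of 0.555.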

How the results depend on the processing

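The alternatives using the share of reads aligned to more than 1 place and replicates 4 to 9 alone were chosen only after the data were seen. The count of 0 genes passing limma's variance test held under every alternative run, and the macrophage r with the injury score kept its sign in all, from 0.0795 to 0.870. The 13 coordinated lists ranged from 4 to 16 and the gene set count of 8 from 0 to 12. Extracellular matrix r ranged from -0.0913 (first principal component as the injury measure) to 0.810 and fatty acid oxidation r, 0.197, from -0.333 to 0.593 (without replicate 1).

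The gene set count was 5 with a mean of at least 100, 1 with Havcr1 alone, 2 with the first principal component, 1 in replicates 4 to 9, and 0 both with camera's estimated correlation and with fry. Leaving out each replicate gave 4 to 9, with 4 without replicate 2 and 5 without replicate 7 or 9. Coordinated lists numbered 5 to 14 when each replicate was left out, with 5 without replicate 1, and 4 in replicates 4 to 9, where fewer samples were tested. The proximal tubule S1 and S2 r, 0.109, was -0.398 at the same total per library, -0.344 with library size as a covariate, -0.161 in replicates 4 to 9, and -0.0676 to 0.282 when each replicate was left out, lowest without replicate 8. Fatty acid oxidation r was -0.333 and -0.161 under the first 2 of these. With Havcr1 alone the clock r, pooled over both sets of replicates and so given only as a check, was 0.0866, above 0 where the injury score's was below 0, and the NF-kB r, 0.662 with the injury score, was -0.266. On the injury score itself DESeq2 called 10 genes with a slope above 0 and 4 below. With the first principal component of the injury list in its place, 1 list score passed, and 1363 genes with slopes above 0 and 1771 below passed adjustment. That component, in a comparison added after the data were seen, ran with the share of reads aligned to more than 1 place (r = 0.678, exact permutation p = 0.0421, rho = 0.767, exact permutation p = 0.0214, r without the 2 farthest 0.787). The cause of these changes was not tested. Among the other values followed, 765 alternative values were unchanged. These include mean levels of named genes, which have no threshold and counted as unchanged within 1 SD. Coordination was followed here only for the 13 lists called at first, so calls gained by other lists are not counted. Against the threshold, 32 values lost a call and 11, of which 10 were DESeq2 slopes, gained one. NF-kB, oxidative phosphorylation and lipogenesis lost their coordination call both with a mean of at least 100 and at the same total per library. A medulla covariate was not run. No paired analysis was possible because the samples form 1 group. Depths of 10757440 to 43071223 reads left genes with a mean under 10, Lcn2 among them, outside the tests.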

Other observations

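All tests of explanations in this part, and the relations between pairs of lists and with the first principal component, were chosen only after the results were seen.

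Relations between pairs of lists were also examined. The podocyte and endothelium scores had a Pearson r of 0.828 (exact permutation p = 8.27e-05, adjusted p = 0.0384), a rho of 0.850 (exact permutation p = 0.00607) and an r of 0.697 without the 2 replicates farthest from the median podocyte score. This was the 1 of 465 pairs that passed adjustment, with 61 at an unadjusted p under 0.05. Proximal tubule S1 and S2 and fatty acid oxidation had an r of 0.940 (exact permutation p = 0.00162, adjusted p = 0.0942; rho 0.683, exact permutation p = 0.0503) and an r of 0.548 without the 2 farthest, so this pair did not pass and its r rests in part on those replicates.

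Single genes outside the fixed rule, named after their values were seen, also varied. Slc16a1, a monocarboxylate transporter, ranged from 719.8 to 9251, the prostaglandin synthase Ptgs2 from 110.8 to 1187, and the trefoil factor Tff3 from 165.3 to 1990. These are values without a test of their own, beyond the variance test that 0 genes passed.

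The first principal component of all tested genes held 52.2% of the variance and was compared with 4 library measures. It had an r of 0.894 with the share of reads aligned to more than 1 place (exact permutation p = 6.83e-04, adjusted p = 0.00107), a rho of 0.767 (exact permutation p = 0.0214) and an r of 0.848 without the 2 farthest replicates. With the share outside genes r was -0.847 (exact permutation p = 8.02e-04, adjusted p = 0.00107), rho -0.917 (exact permutation p = 0.00131) and r without the 2 farthest -0.821. With the share in more than 1 gene r was 0.958 (exact permutation p = 6.61e-05, adjusted p = 2.65e-04), rho 0.975 (exact permutation p = 1.32e-04) and r without the 2 farthest 0.919. This share was used as rounded percentages from 0.09% to 0.13%, so some libraries were tied and these values are approximate. With log2 depth r was 0.562 (exact permutation p = 0.115, adjusted p = 0.115), rho 0.650 (exact permutation p = 0.0666) and r without the 2 farthest 0.334.

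The share of reads aligned to more than 1 place was picked as the covariate after all 4 measures had been seen. With its trend removed, MHC class II genes kept a mean pairwise r of 0.758 (0.812 before, adjusted p = 3.88e-04), and with log2 depth removed 0.760 (adjusted p = 0.00207), which argues against either trend as the whole source of their coordination. The share of reads in more than 1 gene, which had the largest r with the first principal component at 0.958, was not removed. Library quality therefore stays open for MHC class II genes as well. The macrophage list fell from 0.373 to 0.155 (adjusted p = 0.0858) and to 0.268 (adjusted p = 0.283), and the NF-kB list from 0.194 to 0.124 (adjusted p = 0.124) and to 0.159 (adjusted p = 0.286), so library quality and depth stay open there: a trend removed from 9 samples can take real covariation with it. No biological explanation was tested.

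Of the 14 clock genes, 8 parted replicates 1 to 3 from 4 to 9, sets defined from these same values, 6 being higher in the first set, as Nr1d1, and 2 lower, Arntl and Cry1, while Clock, Npas2, Per1, Per2, Hlf and Bhlhe41 overlapped; chance gives 2.38% for a split fixed in advance, which this was not. The clock list score had an r of -0.716 with the share of reads aligned to more than 1 place (exact permutation p = 0.0278, adjusted p = 0.198). Its rho was -0.717 (exact permutation p = 0.0369), and its r without the 2 replicates farthest from the median share -0.879. The mean log2 level of 10 output and repressor genes minus that of Arntl, Clock, Npas2 and Cry1 left a gap of 1.54 between the sets. With the trend on that share removed the gap was 1.31 (SD of replicates 4 to 9, 0.72), which argues against that trend as the whole cause. With the trend on log2 depth removed the gap was 0.63, within the SD of 1.02, so depth is not excluded: replicate 3, the shallowest library, is in the first set, but replicate 9, the next shallowest, had the lowest contrast. A difference in clock phase, such as the hour of collection, would need Arntl and Npas2 to move against Dbp and Nr1d1; the gaps of the 2 pair means were 0.75, though Npas2 alone overlapped, and 1.73. As these genes had been seen first this test could only exclude a phase difference and cannot support it, and the labels give no collection times.

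Kap, the androgen-regulated kidney protein, moved with Slc7a13, Slco1a6, Slc21a4, Hnmt and Akr1c12l1, 6 genes picked because they varied together (mean pairwise r 0.949), whose mean level differed 10.3-fold between replicates, Kap itself running from 6713 to 41901. A larger share of the S3 segment in the tissue piece would move the other 7 S3 genes alike if these measure that share. They differed 1.57-fold and their slope on the 6 was 0.119 (95% interval of a linear fit 0.00878 to 0.229), so they did not keep pace. The S3 list was itself not coordinated (mean pairwise r 0.240, adjusted p = 0.178 against random lists). Whether these 7 genes measure the S3 share is thus not shown, and the slope cannot decide the question. With the trend on the share of reads aligned to more than 1 place removed the 6 genes kept a mean pairwise r of 0.969. A difference in androgen level may be a candidate explanation, as Odc1, an androgen-induced gene in rodent kidney, had an r of 0.964 with the 6 genes (exact permutation p = 4.41e-05; rho = 0.983, exact permutation p = 4.96e-05; r without the 2 farthest 0.927), but Odc1 had also been seen first, so this could exclude the idea and not bear it out. The labels give no sex or hormone level.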
